A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

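The data are 6 Agilent dual-colour tiling arrays of fission yeast (Schizosaccharomyces pombe) used to measure nucleosome turnover. Cells carried a plasmid from which FLAG-tagged histone H3 is made under the invertase (inv1) promoter. Per the labels' protocols, cells in 8% glucose were held with 15 mM hydroxyurea for 4 h, then moved to 4% sucrose with the drug for 2 h so that tagged H3 was made while replication was blocked. They were fixed with 1% formaldehyde for 20 min, sheared to fragments of 400 to 600 bp and immunoprecipitated through the FLAG tag. Per the labels, the immunoprecipitated DNA carried Cy5 and the whole-cell extract DNA carried Cy3 on every array, so there was no dye swap. A higher log2 ratio of Cy5 over Cy3 means more newly made H3 relative to input DNA, and not relative to total H3, which was not measured.

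The arrays fall into wild type (WT, 3 arrays) and 3 mutants with 1 array each, named amo1D, rix1E414K and pob3D. Each mutant shared a slide with 1 WT array: amo1D with WT replicate 1, rix1E414K with WT replicate 2 and pob3D with WT replicate 3. The labels do not say whether the WT samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

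Per the file headers, the authors scanned and quantified the arrays with Agilent Feature Extraction 12.0.3.1, which subtracted a spatially detrended background and applied a linear dye normalization. The deposited scanner files hold these processed signals as linear intensity values for both channels. The deposited series table holds a linear ratio: its values equalled the processed Cy5 over Cy3 to a relative difference of at most 9.05e-09. Its medians were 1.01, 1.01 and 0.998 for the WT replicates, 0.989 for amo1D, 1.02 for rix1E414K and 0.981 for pob3D. Scale, direction and the lack of centring were settled by that match.

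For each probe, log2 of processed Cy5 over processed Cy3 was taken, spots marked as non-uniform or population outliers were removed, and each array was centred on the median of its 43993 probes. The 1227 control spots were left out. No loess or quantile step was applied, because many probes of a ChIP array may shift one way. The linear dye normalization and the centring still remove any shift common to all probes. A change of newly made H3 over the whole genome could therefore not be seen. Each higher or lower value is relative to the median probe of its array. The value of a gene is the mean of the probes whose centre lies in it, with at least 2 probes. The genome was also summarised in 1 kb bins with at least 2 probes. Of 2254 annotated genes with a probe, 1267 long noncoding RNA genes were left out, and 963 genes and 2206 bins were tested.

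Probes are 60 bases long at steps of 50 bases. The build field of the array files is empty, so all coordinates given are those of the array. They were compared with the reference (ASM294v3) by correlating probe signal with GC content. On chromosome II the array numbering ran 900 bases ahead of the reference before a hole in the tiling at 1617470 to 1618511 and 1800 bases ahead after it. The best offset lay within 15 bases of these values in 23 of 23 windows. For the small patches on chromosome III the offset was inferred and not settled by this search. A further sequence on the array, 41210 bases long and named as one more chromosome, follows chromosome II near the mating-type region up to base 25010, in 23 of 39 windows at one offset. It is called the extra sequence here. Its remainder was split by eye into an interior part and a right part.

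The 3 parts of the extra sequence were defined after the data were seen, and their tests are among the 39 of the classes. All other regions were fixed before the data were examined. The constitutive heterochromatin set joins pericentromeric repeats, telomeric regions and the silent mating-type interval, 82 bins in all. Gene lists were fixed at the same time. They were tRNA, glycolytic, core stress, histone, MBF S-phase, ribosomal protein, heterochromatin factor, Mmi1-target meiotic, glucose-repressed, Tf2 retrotransposon and facultative heterochromatin island genes, and phosphate-responsive genes, of which 0 were measured. The genes named were chosen by a rule fixed at the same time. It took amo1, rix1, pob3, inv1 and hht2 always. It took the 10 largest changes per direction among genes past the threshold, or the 5 smallest p-values per direction where fewer than 5 passed. It added up to 2 members of each list with the largest difference, and tlh1 and tlh2. The tlh1 gene, pob3 and rix1 have no probes.

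Genes and bins were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per genotype over all 6 arrays and Benjamini-Hochberg adjustment at 0.05. The residual spread has 2 degrees of freedom, all from WT, so each lone mutant array was assumed to vary like the WT arrays. A permutation test of 1 array against 3 cannot give a one-sided p below 0.25. Region classes and gene lists were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data. Adjusted p-values of classes are over 39 tests, and those of lists over 27. A fit with the slide as a block leaves no residual degrees of freedom, so within-slide differences are given as values with no test.

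The fit was tested on simulated data for amo1D minus WT over 963 genes, of which 200 were changed. It called 69.6% of genes changed by a log2 of 0.5, 95.1% of those changed by 1 and 99.3% of those changed by 2. It called 0.826% of unchanged genes. The simulated genes were independent, with variances drawn from the fitted prior. With fewer changed genes the adjustment is stricter, so these rates need not hold for the data. There, eno101 at -1.61 in rix1E414K did not pass over all genes. The set test was also run with no effect on 82 of 2206 bins that share a level per array with the SD seen among WT, 0.29. The preset correlation then gave an unadjusted p under 0.05 in 86% of 100 simulations, and the estimated correlation in 7%. With independent bins the preset correlation did so in 9%.

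Signal was strong: between 99.8% and 99.9% of probes were well above background in both channels on each array. At most 19 spots per array were removed, and none was saturated. Probes that match several places were kept in the values given, and the share of repeated probes is stated where it matters. The number of arrays limits the precision.

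Alternatives were normexp background correction (offset 50), no background subtraction, loess, quantile normalization, scaling to one median absolute deviation, centring on probes outside all regions, filters on dim and marked spots, the deposited ratios, the median of probes, 1 or 4 probes as the minimum, probes with 1 match, the residual from a trend on WT (span 0.3), robust and trended moderation, each WT replicate left out, thresholds of 0.01 and 0.1, and other feature sizes. Normexp and the fit without background subtraction used the median signal of each spot, because the files hold no mean signal. The trend on WT was drawn through euchromatic features. All bins of the central core of centromere 2, at WT means of -3.74 to -3.13, lie below the lowest euchromatic bin, at -1.44. Residuals of the core thus use the end value of the trend and cannot decide whether the core differs. Including long noncoding RNA genes, adding the extra sequence to the constitutive set, and a trend on WT without bins of tRNA genes, were chosen after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, data.table (version 1.17.8) and matplotlib 3.10.9 were also used.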

Results

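Newly made histone H3 was mapped on 6 tiling arrays of fission yeast held in a hydroxyurea block, to ask whether nucleosome turnover over heterochromatin depends on Amo1, a protein of the nuclear rim. The arrays compare WT (n = 3) with a deletion of amo1, with rix1E414K, a mutant of a subunit of the rixosome, a ribosome biogenesis complex, and with a deletion of pob3, which encodes a subunit of the histone chaperone FACT. Each mutant had 1 array and so no replicate of its own. The arrays cover chromosome II from 1000011 to 3049820 and its right end from 4491601 to 4541560. They also cover the left end of chromosome III from 1 to 49970, patches at inv1 and nmt1 on chromosome III and at hrp1 on chromosome I, and the extra sequence. Median processed intensity was 1018 to 1150 in Cy5 and 993.2 to 1145 in Cy3. The SD of the log2 ratio over probes was 0.49, 0.46 and 0.41 in the WT replicates, 0.45 in amo1D, 0.47 in rix1E414K and 0.37 in pob3D.

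The amo1 gene was missing from the whole-cell extract of the amo1D array. Over its 31 probes (chromosome II, 3030461 to 3032020), log2 Cy3 against the array median was -9.41 in amo1D, and 2 of the 31 probes were well above background. The WT replicates had -0.91, -0.86 and -0.88, rix1E414K had -0.81 and pob3D had -0.72. Probes without signal in amo1D started between 3030361 and 3031961. With both channels at background there, the log ratio of amo1 in amo1D has no meaning as turnover. The labels of pob3D and rix1E414K could not be checked in this way, because neither gene has a probe.

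Among the genes with the highest ratios in WT, the mean log2 ratio was 1.51 ± 0.28 (SD, n = 3) at hht2, which encodes histone H3 (II, 1366011 to 1366720), and 1.14 ± 0.42 at inv1, whose promoter drives the tagged histone. It was 1.05 ± 0.49 at the thiamine-repressed gene nmt1 and 0.95 ± 0.33 at the polyubiquitin gene ubi4, 74.1% of whose probes match several places. Per the labels, the plasmid also carries the inv1 promoter and an H3 gene.

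Averaged over the WT arrays, the central core and the constitutive heterochromatin classes lay below euchromatin, by an amount that varied between arrays. On replicate 3 the telomeric region, at 0.025, was not below euchromatin, at 0.024. Euchromatic bins averaged 0.036 ± 0.011 (SD, n = 3). The central core of centromere 2 (II, 1621061 to 1630970) averaged -3.50 ± 0.17, and the pericentromeric repeats (1603161 to 1646570, outside the core) -0.83 ± 0.36. Without a measure of total H3, the low ratio of the core does not separate slow turnover from a low H3 content. The silent mating-type interval (2131011 to 2138920) averaged -0.49 ± 0.13, the telomeric region at the right end (4502401 to 4541560) -0.22 ± 0.28 and the subtelomere next to it (4491601 to 4502410) -0.38 ± 0.16. The first 15 kb of chromosome III, within ribosomal DNA repeats, averaged -0.26 ± 0.25, the 24 tRNA genes -1.002 ± 0.21 and the Tf2 retrotransposons 0.57 ± 0.17. The constitutive heterochromatin set averaged -0.50 ± 0.29. A WT array taken alone differed from the other 2 by 0.17, -0.50 and 0.33 over that set for replicates 1, 2 and 3. Repeated probes made up 92.8% of the pericentromeric, 81.2% of the telomeric, 71.8% of the subtelomeric and 66.5% of the mating-type probes.

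**Figure D1:**
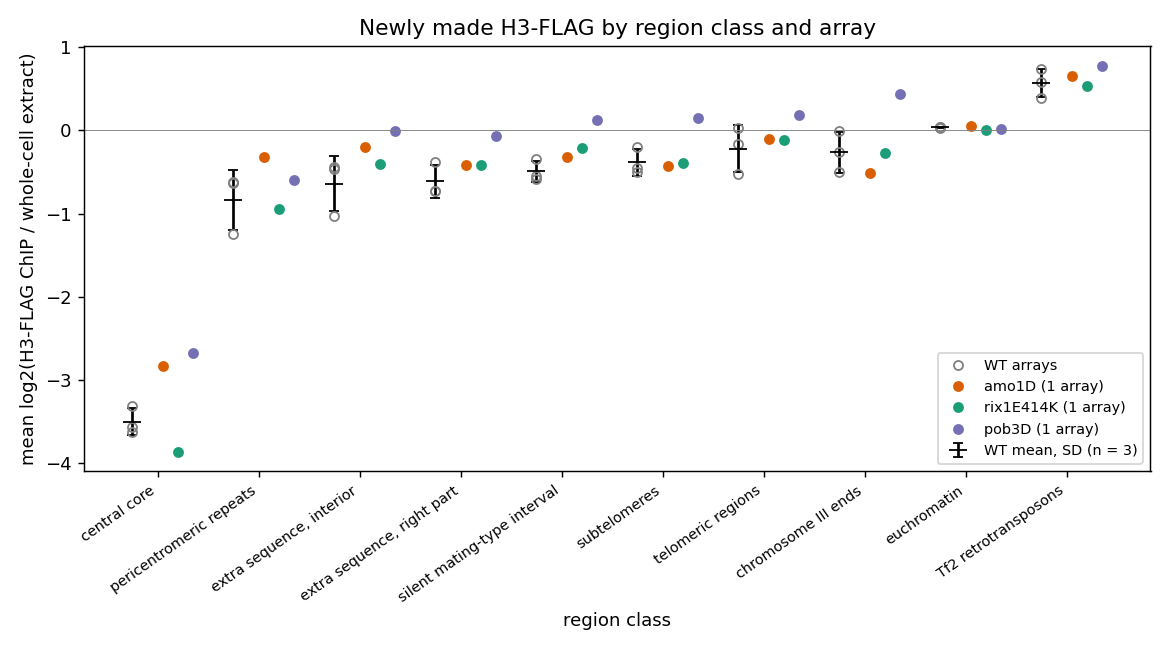
Mean log2 ratio of H3-FLAG ChIP (Cy5) over whole-cell extract (Cy3), centred on each array's median, for each region class on each array, with the WT mean and its SD over 3 arrays. The central core is lowest in every group, at -3.50 in WT, -2.84 in amo1D, -3.86 in rix1E414K and -2.67 in pob3D.

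In amo1D, the ratio of newly made H3 to input DNA was higher than in WT over centromere 2, while the telomeric region and the subtelomere differed from WT by less than the WT spread. The pericentromeric repeats were 0.51 higher on the log2 scale (1.42-fold), with 32 of 34 bins above all WT arrays. The central core was 0.67 higher (1.59-fold), with 10 of 10 bins above all WT arrays. The silent mating-type interval was 0.18 higher (adjusted p = 0.0399 preset, p = 0.286 with an estimated correlation), the telomeric region 0.12 higher and the subtelomere differed by -0.051. The whole constitutive set was 0.29 higher (1.22-fold), within the WT SD of 0.29, with 44 of 82 bins above all WT arrays. Within the slide, against WT replicate 1, the differences were 0.17 for the set, 0.30 for the pericentromeric repeats and 0.73 for the core. Without WT replicate 2 the set differed by 0.12, the pericentromeric repeats by 0.30 and the telomeric region by -0.034, and without replicate 3 the subtelomere differed by 0.042. The set was 0.18 with genes in place of bins, and the repeats 0.31 as a residual from the trend on WT. The mating-type call ended under 5 planned settings, with the lowest value, 0.044, as that residual. The low end of that trend rests on 6 bins, all with tRNA genes; without such bins, a setting added after the data were seen, the residuals were 0.58 for the repeats and 0.21 for the interval. In the separate channels, amo1D minus WT was 1.24 in Cy5 and 0.58 in Cy3 over the core, where the WT SD was 0.61 and 0.78. The Cy3 difference of the core was thus within the WT SD. Over the pericentromeric repeats the differences were 0.59 in Cy5 and 0.083 in Cy3, both within the WT SD of their channel.

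The set passed limma's camera at the preset correlation (adjusted p = 1.31e-08) but not with an estimated correlation (p = 0.379). The pericentromeric repeats had an adjusted p of 6.37e-13 preset and p = 0.196 with an estimated correlation, and the core 1.03e-14 and p = 0.107. No class passed Benjamini-Hochberg adjustment with an estimated correlation in any mutant. The core exceeded the largest difference of a lone WT array (0.28), and the pericentromeric repeats and the constitutive set did not (0.62 and 0.50). Here and below, this comparison rests on 3 WT arrays and is not a test, so exceeding it does not set aside variation between arrays. The core difference depended on the processing: it was -0.50 under normexp, 0.38 without background subtraction, 1.15 after scaling to one median absolute deviation, and 0.092 as a residual or 0.79 with the trend without bins of tRNA genes. The chromosome III end was 0.26 lower in amo1D (adjusted p = 1.45e-04 preset, p = 0.109 with an estimated correlation), less than the 0.37 by which a lone WT array differed, and -0.13 without WT replicate 2, -0.42 after quantile normalization and -0.16 after scaling. Over the extra sequence, whose parts were defined after the data were seen, amo1D was 0.44 higher in the interior, 0.20 in the right part and 0.18 in the part shared with chromosome II (adjusted p = 1.17e-04, 0.0387 and 4.65e-06 preset, p = 0.275, 0.450 and 0.0884 with an estimated correlation). In the shared part, which holds a stretch near background from 21551 to 22660, Cy5 differed by 0.030 and Cy3 by -0.15. Within the slide the ratio differences were 0.27, 0.31 and 0.19, whereas the interior was 0.25 without WT replicate 2 and the right part 0.31 without replicate 3. The right-part call ended without replicates 1 and 2 in turn (0.14 each) and as a residual (0.089, or 0.25 with the trend without bins of tRNA genes).

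The ratio was higher in amo1D than in WT over glycolytic and tRNA genes. Over tRNA genes the WT SD was 0.21. WT replicate 2 alone differed there from the mean of the other WT arrays by more than amo1D differed from WT. All 4 glycolytic genes lay above all WT arrays, by 0.58 on average and by 0.38 within the slide (camera adjusted p = 0.00194 preset, p = 0.153 with an estimated correlation). The largest differences were 0.83 (SE 0.16) at tdh1, for glyceraldehyde-3-phosphate dehydrogenase (II, 2809411 to 2810870), and 0.67 (SE 0.37) at eno101, for enolase. Adjusted over the list alone, 1 glycolytic gene, tdh1, passed in limma, and over all genes tested 0 did. Of the 24 tRNA genes, 15 lay above all WT arrays, with a mean difference of 0.31 and of 0.43 within the slide (camera adjusted p = 1.97e-08 preset, p = 0.266 with an estimated correlation). They included SPBTRNAARG.07 at 0.44 (SE 0.094), SPBTRNAALA.11 at 0.54, SPBTRNAALA.09 at 0.53 and SPBTRNAGLY.08 at 0.48, the latter 3 from repeated probes only. The 24 ribosomal protein genes differed by 0.081 on average and by 0.040 within the slide (camera preset adjusted p = 0.0112, p = 0.254 with an estimated correlation), with rpl26 at 0.29 and rpl1701 at 0.27.

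Other lists in amo1D did not pass camera at either correlation. The 5 core stress genes averaged 0.38, with the small heat-shock gene hsp16 at 1.22 (SE 0.85) and ish1 at 0.35. The 3 histone genes averaged 0.14, with hht2 at 0.46 and pht1, for the variant H2A.Z, at -0.13. Of the 2 MBF S-phase genes, yox1 was at 0.38 and the replication licensing gene cdc18 at 0.15. Of the 2 heterochromatin factor genes, clr1 was at -0.17 and tas3 at -0.063. The meiotic genes mei4, the only measured island gene, and rec8 were at 0.19 and 0.010. The elements Tf2-10 and Tf2-9 were at 0.097 and 0.079, inv1 at 0.42 and the telomere-linked helicase gene tlh2 at 0.21, the latter from 92.5% repeated probes. The noncoding RNA gene SPNCRNA.369, inside the central core, was at 0.50 (SE 0.12), but at -0.22 under normexp, -0.18 after quantile normalization and -0.038 as a residual. The lowest p-values among lower genes were at SPBC31A8.02 (-0.37), wdr7 (-0.26), the ubiquinone synthesis gene coq8 (-0.24), ppk31 (-0.27) and rhp18 (-0.23).

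No gene and no bin differed between amo1D and WT at an adjusted p of 0.05 in limma. The smallest adjusted p over genes, 0.282, was that of the deleted amo1 itself; the smallest of the other genes was 0.83, and over bins it was 0.793. At an unadjusted p of 0.05, 34 genes, amo1 among them, were higher and 13 lower, where 48.15 in all would be called by chance, and 61 bins, 2 of them over amo1, were higher and 17 lower.

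In rix1E414K, the ratio of newly made H3 to input DNA was lower than in WT over the central core and tRNA genes, and the constitutive set as a whole was close to the WT mean. The core was lower by a log2 difference of -0.36 (0.779-fold), with 10 of 10 bins below all WT arrays. Both channels were higher there than in WT, by 0.57 in Cy5, within the WT SD of 0.61, and 0.94 in Cy3, where the WT SD was 0.78. The set differed by 0.031, the pericentromeric repeats by -0.12 and the telomeric region by 0.11. The silent mating-type interval was 0.28 higher (1.22-fold), with 4 of 8 bins above all WT arrays, but 0.031 with probes of 1 match, which ended the call, and 0.48 as a residual from the trend on WT. Within the slide, against WT replicate 2, the differences were 0.36 for the set, 0.30 for the pericentromeric repeats, 0.41 for the telomeric region, 0.37 for the mating-type interval and -0.55 for the core. WT replicate 2 was the lowest WT array over the set, and without it the set differed by -0.13, the pericentromeric repeats by -0.33 and the telomeric region by -0.045. Without WT replicates 1 and 3 in turn the pericentromeric repeats differed by -0.012 and -0.018, and without replicate 3 the telomeric region differed by 0.23. The pericentromeric repeats (adjusted p = 0.0387 preset, p = 0.629 with an estimated correlation) lost their call under 5 planned settings, with -0.0026 under loess, and turned to 0.14 as a residual, or 0.026 with the trend without bins of tRNA genes.

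The set did not pass camera (adjusted p = 0.461 preset, p = 0.892 with an estimated correlation). The core had an adjusted p of 3.94e-07 preset and p = 0.208 with an estimated correlation, and the mating-type interval 0.00159 and p = 0.161. Both exceeded the largest difference of a lone WT array, 0.28 for the core and 0.22 for the interval. The core lies below every bin through which the trend on WT was drawn, so its residuals cannot settle a direction. The core difference was 0.22 as a residual, the opposite direction, but -0.15 with the trend without bins of tRNA genes. Its call ended with that trend and after scaling (-0.047), while it was -0.80 under normexp and -0.59 without background subtraction. Over the extra sequence, rix1E414K was 0.24 higher in the interior, 0.20 in the right part and 0.13 in the shared part (adjusted p = 0.0108, 0.0459 and 0.00175 preset, p = 0.421, 0.469 and 0.164 with an estimated correlation). In the shared part Cy5 differed by 0.042 and Cy3 by -0.082. Within the slide the ratio differences were 0.63, 0.31 and 0.17, whereas the interior was 0.050 without WT replicate 2, which ended its call, and 0.39 as a residual. The right part was 0.31 without replicate 3 and 0.36 as a residual, and its call ended under 4 settings, with the lowest value, 0.11, under normexp.

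In rix1E414K, 23 of 24 tRNA genes lay below all WT arrays, with a mean difference of -0.46, of -0.75 under normexp and of -0.70 within the slide (camera adjusted p = 7.94e-14 preset, p = 0.182 with an estimated correlation). Adjusted over the list alone, 1 passed in limma, SPBTRNAARG.07 at -0.56 (SE 0.094), and over all genes 0 did. Others were SPBTRNAARG.06 at -0.64, and SPBTRNALEU.06 at -0.74 and SPBTRNALEU.07 at -0.71 from repeated probes only. Of the 4 glycolytic genes, 3 passed adjusted over the list alone and lay below all WT arrays, and the fourth, pfk1, for phosphofructokinase, named after its value was seen, lay above all WT arrays at 0.24 (SE 0.10). The list mean was -0.77, or -0.86 within the slide (preset adjusted p = 0.039, p = 0.245 with an estimated correlation). Under normexp the list mean was -0.30 and no longer passed. The other values were -1.61 (SE 0.37) at eno101, -1.20 (SE 0.27) at fba1, for fructose-bisphosphate aldolase, and -0.52 at tdh1. These genes varied among WT arrays too, with 0.60, 0.38 and -0.34 at eno101.

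The 5 core stress genes averaged -0.65 in rix1E414K, which did not pass (preset adjusted p = 0.12). The value at hsp16 was -2.40 (SE 0.85), where the WT SD was 1.15, and at the glutathione peroxidase gene gpx1 it was -0.42. Histone genes averaged -0.21, with the H4 gene hhf2 at -0.32 and hht2 at -0.17. The MBF S-phase genes yox1 and cdc18 were at -0.25 and -0.17, the heterochromatin factor genes clr1 and tas3 at 0.12 and 0.089, rec8 at 0.11, mei4 at -0.030, inv1 at -0.47 and tlh2 at 0.30. Ribosomal protein genes averaged 0.033, with rpl401 at 0.18 and rps2501 at -0.18, and Tf2-10 and Tf2-9 were at -0.038 and -0.023. Among higher genes the lowest p-values were at gcv3 (0.31), for a glycine cleavage protein, prs1 (0.28), slm9 (0.26), for a subunit of the HIRA histone chaperone, sec6102 (0.26) and the autophagy gene atg9 (0.25). Among lower genes they were, besides tRNA genes, at SPBC31A8.02 (-0.51), dbl7 (-0.39) and the ribosomal RNA gene SPRRNA.40 (-0.50).

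No gene and no bin passed an adjusted p of 0.05 in limma for rix1E414K (smallest adjusted p 0.714 over genes and 0.873 over bins). At an unadjusted p of 0.05, 14 genes were higher and 43 lower, against 48.15 by chance, and 29 bins were higher and 89 lower. Without WT replicate 3, 4 genes passed, at adjusted p from 0.0444 to 0.0447: eno101 (-1.88), fba1 (-1.39), hsp16 (-3.05) and snoU14 (-1.39).

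In pob3D, the ratio of newly made H3 to input DNA was higher than in WT over most of the heterochromatin tiled, in part with a lower Cy3 signal. The subtelomere was 0.53 higher (1.44-fold), with 11 of 11 bins above all WT arrays, and the silent mating-type interval 0.61 higher (1.53-fold), with 7 of 8. That interval holds the stretch from 2133111 to 2134220, where both channels were near background, and 136 of its 158 probes were above background on all arrays. With those probes only, it was 0.73 higher in pob3D, 0.27 in amo1D and 0.35 in rix1E414K. The telomeric region was 0.41 higher, with 27 of 40 bins above all WT arrays, the chromosome III end 0.70 higher, with 12 of 15, and the central core 0.83 higher (1.78-fold), with 10 of 10. The pericentromeric repeats were 0.23 higher, with 12 of 34, where 29.2% of all bins lay above all WT arrays. Over these repeats and the telomeric region a lone WT array differed by more than pob3D did. The constitutive set was 0.36 higher (1.28-fold), with 46 of 82 bins above all WT arrays and 0 below. Within the slide, against WT replicate 3, the differences were 0.14 for the set, 0.34 for the subtelomere, 0.47 for the mating-type interval, 0.16 for the telomeric region, 0.95 for the chromosome III end, 0.96 for the core and 0.031 for the pericentromeric repeats. Without WT replicate 2 the set differed by 0.19, the telomeric region by 0.26 and the pericentromeric repeats by 0.026. Under loess these were 0.19, 0.25 and 0.034, and both settings ended the call of the repeats.

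The set passed camera at the preset correlation (adjusted p = 2.53e-12) and not with an estimated correlation (p = 0.303). At the preset and then the estimated correlation, the subtelomere gave an adjusted p of 3.94e-07 and p = 0.0915, the mating-type interval 1.64e-05 and p = 0.0979, and the chromosome III end 5.85e-07 and p = 0.0678. The core gave, for the preset and the estimated correlation, 8.05e-13 and p = 0.123, the telomeric region 1.60e-10 and p = 0.295, and the pericentromeric repeats 0.00106 and p = 0.473. The subtelomere, mating-type interval, chromosome III end and core exceeded the largest difference of a lone WT array (0.28, 0.22, 0.37 and 0.28). The constitutive set, telomeric region and pericentromeric repeats did not (0.50, 0.46 and 0.62). In the separate channels, pob3D minus WT was 0.64 in Cy5 and 0.076 in Cy3 over the subtelomere, and 0.17 in Cy5 and -0.48 in Cy3 over the mating-type interval. Within the slide it was 0.13 in Cy5 and -0.24 in Cy3 over the subtelomere, and -0.066 and -0.56 over the interval. Over the core Cy5 and Cy3 differed by 0.89 and 0.028 from the WT mean and by 0.40 and -0.58 within the slide, and over the chromosome III end by 0.69 and -0.046, and 0.18 and -0.79. Within the slide Cy5 was lower in pob3D over the set (-0.054) and the pericentromeric repeats (-0.17). Quantile normalization brought the differences to -0.040 in the pericentromeric repeats and 0.23 in the set. As residuals from the trend on WT the core, repeats and set were at 0.29, -0.067 and 0.19, or at 0.17, -0.17 and 0.14 with the trend without bins of tRNA genes, which ended the call of the core. The core was 0.48 without background subtraction and 0.074 under normexp, which ended its call. Over the extra sequence, pob3D was 0.63 higher in the interior, 0.54 in the right part and 0.29 in the shared part (adjusted p = 1.00e-04, 1.17e-04 and 2.43e-06 preset, p = 0.270, 0.236 and 0.0840 with an estimated correlation), and 0.43, 0.31 and 0.23 within the slide. In these parts Cy3 differed from the WT mean by -0.30, -0.46 and -0.34 and Cy5 by 0.37, 0.12 and -0.015, and within the slide Cy5 differed by -0.069, -0.16 and -0.094. As residuals the interior and right part were 0.40 and 0.32, or 0.35 and 0.23 with the trend without bins of tRNA genes. The Tf2 bins were 0.21 higher (adjusted p = 0.0224 preset, p = 0.435 with an estimated correlation), 0.38 within the slide, 0.37 as a residual, -0.098 under loess and 0.12 without WT replicate 3, which ended the call.

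In pob3D, 18 of 24 tRNA genes lay above all WT arrays, with a mean difference of 0.29 and of 0.41 within the slide (camera adjusted p = 3.64e-07 preset, p = 0.30 with an estimated correlation). WT replicate 2 alone differed from the mean of the other WT arrays over these genes by more than 0.29. Adjusted over the list alone, 0 passed in limma, with SPBTRNAVAL.05 at 0.55 and SPBTRNAVAL.06 at 0.46, both from repeated probes. Other lists did not pass. The glycolytic genes averaged -0.079, with fba1 at -0.44 and tdh1 at 0.16, and the core stress genes -0.077, with ish1 at -0.57 and gpx1 at -0.56. Histone genes averaged -0.13, with hht2 at -0.26 and hhf2 at -0.19, and the heterochromatin factor genes clr1 and tas3 were both at -0.21. The MBF S-phase genes yox1 and cdc18 were at 0.12 and 0.027, rec8 at -0.16, mei4 at 0.12, inv1 at -0.10 and tlh2 at 0.15. Ribosomal protein genes averaged 0.017, with rpl26 at 0.29 and rps1002 at 0.26. Tf2-9 and Tf2-10 were at 0.21 and 0.20.

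Among single genes in pob3D, the lowest p-values among higher values were at SPNCRNA.369 in the central core (0.83, SE 0.12, but -0.049 under normexp and -0.021 after quantile normalization), aim19 (0.49), llp1 (0.39), tam9 (0.36) and git5 (0.41), for a G protein beta subunit. Among lower values they were at sfc3 (-0.44, SE 0.080), for a subunit of transcription factor TFIIIC, orc1 (-0.42), for an origin recognition subunit, SPBC337.11 (-0.39), pgs1 (-0.39) and ubi4 (-1.20, SE 0.26). No gene and no bin passed an adjusted p of 0.05 in limma (smallest adjusted p 0.389 over genes and 0.272 over bins). At an unadjusted p of 0.05, 52 genes were higher and 70 lower, against 48.15 by chance, and 153 bins were higher and 97 lower. A lone WT array set against the other 2 gave 17 higher and 7 lower genes for replicate 1, 39 and 31 for replicate 2, and 13 and 47 for replicate 3.

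**Figure D2:**
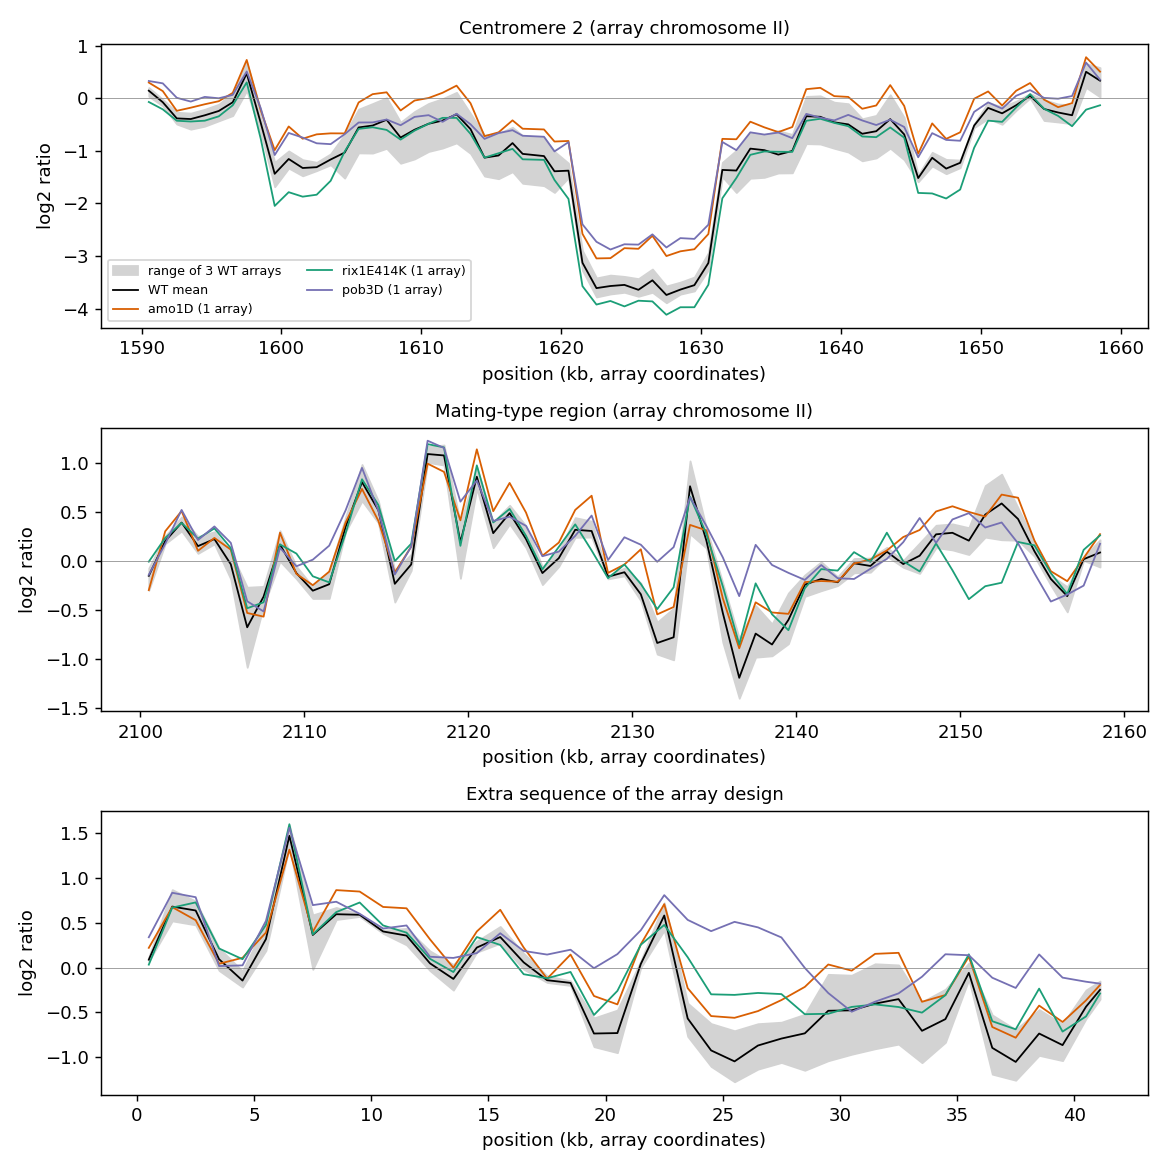
Log2 ratio of H3-FLAG ChIP over whole-cell extract along array coordinates, for the WT range of 3 arrays and each mutant, over centromere 2, the mating-type region of chromosome II and the extra sequence. Peaks at 2133111 to 2134220 and at 21551 to 22660 of the extra sequence lie where both channels were near background on all arrays and carry no information.

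Set against each other, the mutants differed in the constitutive set by less than the 0.50 by which a lone WT array differed from the other 2. The difference of rix1E414K minus amo1D was -0.26, but 0.19 once each mutant was taken against the WT array of its slide (camera adjusted p = 0.00724 preset, p = 0.636 with an estimated correlation). For pob3D minus amo1D it was 0.069 (0.035 after scaling), and -0.036 against slide controls (adjusted p = 0.0192 preset, p = 0.676 with an estimated correlation). For pob3D minus rix1E414K it was 0.33, and -0.22 against slide controls (adjusted p = 1.28e-06 preset, p = 0.437 with an estimated correlation). The direction of all 3 thus turned with the control. The p-values given are those of the direct differences, and the values against slide controls have no test. No gene or bin passed an adjusted p of 0.05 in limma in these contrasts. At an unadjusted p of 0.05 the genes higher and lower were 58 and 80 for rix1E414K minus amo1D, 21 and 40 for pob3D minus amo1D, and 83 and 113 for pob3D minus rix1E414K.

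Across the 2206 bins, which are not independent replicates, the differences from WT in amo1D and rix1E414K ran in opposite directions (Pearson r = -0.379, Spearman rho = -0.312, covariance -0.013). Shared WT controls alone gave r = 0.248 and a covariance of 0.00823 in 200 simulations with no effect. The simulated bins were independent, so the simulation does not cover patterns that bins of an array share. It cannot tell an effect of the mutants from such patterns. With a different WT array as the control of each mutant, r lay between -0.621 and -0.286 over the 6 assignments. For amo1D and pob3D r was 0.26, rho 0.307 and the covariance 0.0114, and distinct controls gave -0.139 to 0.311. For rix1E414K and pob3D r was 0.0174, rho -0.0776 and the covariance 0.000828, with -0.283 to 0.0921 for distinct controls. Between arrays, r was 0.885, 0.884 and 0.833 among WT pairs, 0.913 for amo1D with WT replicate 1 and 0.91 for rix1E414K with WT replicate 3 of another slide.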

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

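All tests of explanations in this part were chosen after the results were seen, apart from the one on the lowest euchromatic bins. Some of them use planned settings: normexp, the residual from the trend on WT and leaving out a WT replicate. The trend without bins of tRNA genes and the filters on differences between mutants were also chosen after the results were seen. The filters were a preset camera adjusted p under 0.05, one sign with and without the slide's WT array, and a size beyond that of any lone WT array both ways. A lone WT array is set against the mean of the others, whereas these contrasts combine single arrays only. They vary more, most of all against slide controls, so meeting the filters does not place a difference beyond variation between arrays. Of the 39 class contrasts tested, 6 outside euchromatin met them, and so did euchromatin for rix1E414K minus amo1D, at -0.042 with either control; none passed Benjamini-Hochberg adjustment with an estimated correlation.

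At the central core of centromere 2, rix1E414K lay below amo1D by a log2 difference of -1.03 and pob3D lay above rix1E414K by 1.19 (p = 0.131 and p = 0.124 with an estimated correlation). Under normexp these were -0.30 and 0.87. As residuals from the trend on WT they were 0.13, the opposite direction, and 0.067. With the trend without bins of tRNA genes they were -0.94 and 0.32. The core lies below the range of both trends, so these residuals cannot settle the direction. At the chromosome III end, pob3D exceeded amo1D by 0.96 and rix1E414K by 0.72 (p = 0.0349 and p = 0.113 with an estimated correlation), the latter by 0.42 under loess and 0.44 as a residual. Compared with amo1D, pob3D was also higher by 0.44 in the silent mating-type interval and by 0.58 in the subtelomere (p = 0.127 and p = 0.072 with an estimated correlation). Against slide controls the 6 differences were -1.28, 1.51, 1.20, 1.21, 0.23 and 0.32 in that order. With the trend without bins of tRNA genes the mating-type difference was 0.13, below the 0.22 of a lone WT array. The subtelomere difference was then 0.43.

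The first pattern weighed is the higher ratio of pob3D over heterochromatin. A narrower range of log ratios on that array is argued against in the mating-type interval. The residual there from the euchromatic trend on WT was 0.41, or 0.33 with the trend without bins of tRNA genes. A narrower range could account for the pericentromeric repeats, where these residuals were -0.067 and -0.17. Less DNA from the locus in the whole-cell extract may underlie the mating-type difference, where Cy3 differed by -0.48, and stays open for the subtelomere and telomeric region, where the lower Cy3 difference was 0.076, within the WT SD, and where Cy3 was -0.24 and -0.14 against the slide's WT array. A lone WT array differed by up to 0.50 over the constitutive set, more than pob3D did. Over the mating-type interval a lone WT array differed by up to 0.22, less than pob3D did. With only 3 WT arrays, the largest of their differences cannot set aside variation between arrays at the interval. Such variation stays open for both. A change of turnover with the loss of this FACT subunit stays open and was not replicated.

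The second pattern is that the central core and tRNA genes shifted the same way within each mutant, up in amo1D and pob3D and down in rix1E414K. Among WT arrays, replicate 2 was likewise the highest over both, by 0.28 over the core. The core and tRNA genes thus also moved together between arrays of 1 genotype. If low ratios had become deeper or shallower across an array, the lowest euchromatic bins without tRNA genes would have followed the core. They did so in 2 of 3 mutants, but only pob3D (0.32) moved beyond the WT SD of 0.11, with rix1E414K at -0.089 and amo1D at -0.059, so an array-wide change and a change at these loci cannot be told apart. As residuals from the trend on WT the core stood at 0.092, 0.22 and 0.29 in amo1D, rix1E414K and pob3D. The low end of that trend rests on 6 bins with tRNA genes, and without such bins the core stood at 0.79, -0.15 and 0.17. The lowest euchromatic bin had a WT mean of -1.44, or -1.02 without tRNA genes, and all core bins lay at -3.74 to -3.13. Both trends reach the core only as a constant carried on from their ends, so these residuals cannot decide. Background correction may contribute, since the core difference of amo1D was -0.50 under normexp, and a difference by genotype was not tested beyond these single arrays.

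The third pattern is that WT replicate 2 lay below the other WT arrays over the pericentromeric and telomeric repeats, by -0.62 and -0.46. Saturation of bright multi-copy probes is argued against by the chromosome III end, which was 0.37 higher in replicate 2. More repeat DNA in its whole-cell extract is argued against by Cy3 over the pericentromeric repeats, at -0.49. An effect of slide 2 was not seen in the telomeric region, where rix1E414K was at -0.045 against the other WT arrays, if the mutation itself moved nothing there, but stays possible for the pericentromeric repeats, at -0.33. All 3 arrays are WT, so no biological explanation was tested.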

How the results depend on the processing

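Only the addition of long noncoding RNA genes and of the extra sequence, and the trend without bins of tRNA genes, were chosen after the data were seen; the other settings below were planned. The count of genes past the threshold stayed at 0 under 21 of 21 planned settings in amo1D and in pob3D. In rix1E414K it was 0 in 20 of 21 and 4 without WT replicate 3, so that leaving out WT replicates gave 0 to 4. The constitutive set stayed higher than WT under all 22 planned settings in amo1D (0.12 to 0.40) and pob3D (0.14 to 0.47). With an estimated correlation the differences of 0.29 and 0.36 no longer passed (p = 0.379 and p = 0.303), the cause being the correlation between bins. With the extra sequence added, the set differed by 0.30, 0.064 and 0.40 in amo1D, rix1E414K and pob3D. No paired analysis was possible, because the pairing is by slide and each mutant shared a slide with a single WT array. The slide block gave no gene counts, since it leaves no residual degrees of freedom. Robust or trended moderation was not run for the set results. About 99.8% of probes were well above background. Background correction still mattered for the central core, at 0.67 in amo1D but -0.50 under normexp. The single array per mutant limits every comparison. Of other results, the cause of each change below was not tested.

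The constitutive set in rix1E414K had no stable direction: it was -0.024 under normexp, -0.036 with probes of 1 match, -0.066 with genes in place of bins, 0.040 with single probes (now past the threshold), 0.17 as a residual from the trend on WT (also past it), 0.12 with the trend without bins of tRNA genes (also past it), 0.36 within the slide and -0.13 to 0.14 when a WT replicate was left out, both ends past the threshold. Its pericentromeric repeats were 0.14 as a residual and 0.30 within the slide, its central core 0.22 as a residual. With the trend without bins of tRNA genes, its pericentromeric repeats were 0.026, its subtelomere 0.053, its chromosome III end 0.11 and its Tf2 elements 0.10, the Tf2 elements of amo1D -0.021 and the pericentromeric repeats of pob3D -0.17. Its subtelomere was 0.00053 after quantile normalization, 0.0051 after scaling to one median absolute deviation, 0.064 with probes of 1 match, 0.0041 with the median of probes, 0.059 as a residual and -0.064 to 0.087 without a WT replicate. Its chromosome III end was 0.070 under loess, 0.054 after quantile normalization, 0.031 after scaling, 0.15 as a residual and -0.14 to 0.11 without a WT replicate. Its Tf2 elements were 0.014 under normexp, 0.00092 without background subtraction, 0.26 under loess, 0.059 after quantile normalization, 0.10 as a residual and -0.12 to 0.054 without a WT replicate. As a list, they were 0.020 under normexp and -0.12 to 0.063 without a WT replicate. Its telomeric region ranged from -0.045 to 0.23 without a WT replicate.

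In amo1D the central core was -0.50 under normexp and -0.0014 after quantile normalization, which holds the core, lowest on every array, near 0 in all mutants by construction. SPNCRNA.369, within that core, was -0.22 under normexp, -0.18 after quantile normalization and -0.038 as a residual in amo1D, and -0.049 and -0.021 under the former pair of settings in pob3D. The Tf2 elements in amo1D were -0.021 after quantile normalization, -0.021 as a residual and -0.0089 to 0.16 without a WT replicate, or -0.0017 to 0.18 as a list. Without a WT replicate the telomeric region in amo1D ranged from -0.034 to 0.24 and its subtelomere from -0.11 to 0.042. In pob3D the pericentromeric repeats were -0.040 after quantile normalization and -0.067 as a residual, the central core -0.00083 after quantile normalization, and the Tf2 elements -0.098 under loess. In pob3D the Mmi1-target genes were 0.0047 after scaling and -0.023 to 0.0094 without a WT replicate, the glycolytic genes -0.23 to 0.021 and the core stress genes -0.26 to 0.030. The difference of pob3D minus amo1D in the constitutive set was 0.069 to 0.069 when a WT replicate was left out, since it does not use the WT means, but 0.035 after scaling and 0.076 under normexp, and it no longer passed without WT replicate 2 (p = 0.148 at the preset correlation). The difference of amo1D from the WT mean in log2 Cy3 of amo1 was -1.38 under normexp and -7.73 after scaling.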

Other observations

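The windows and groups in this part, apart from the gene types of the annotation, were chosen after the values were seen, and no test was run on them. A window of the extra sequence, from 19001 to 29010 without its silent stretch, had a mean log2 ratio of -0.80 ± 0.23 (SD, n = 3) in WT. From 19001 to 25010 it follows chromosome II from 2130561 on, largely within the silent mating-type interval. These bins thus in part repeat the values of that interval and are no separate locus. In all 3 mutants 8 of 8 bins of the window lay above all WT arrays. The differences were 0.41 in amo1D, 0.50 in rix1E414K and 1.10 in pob3D, and 0.43, 0.72 and 0.86 within the slides. A lone WT array differed from the other 2 by at most 0.35. In pob3D the channels split this into -0.91 in Cy3 and 0.22 in Cy5, while in amo1D and rix1E414K Cy5 differed by 0.41 and 0.40 and Cy3 by 0.0018 and -0.10. In the brighter stretch from 29001 to 34010 the differences were 0.47, 0.022 and 0.17, all below the 0.72 of a lone WT array.

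Ribosomal RNA genes (14, on chromosomes II and III) averaged -0.19 ± 0.34 in WT and were 0.53 higher in pob3D, or 0.86 within the slide. In amo1D they differed by -0.020 and in rix1E414K by -0.28. The short genes SPRRNA.50 and SPRRNA.51 in the chromosome III repeats had -1.05 and -1.04 in WT and 0.0016 and 0.070 in pob3D, all from repeated probes. The 5 tRNA genes of centromere 2 differed from WT by 0.46 in amo1D, -0.59 in rix1E414K and 0.40 in pob3D, and the 19 elsewhere by 0.27, -0.42 and 0.26. In the inv1 patch (III, 1724400 to 1727359) the log2 ratio was 1.5, 1.05 and 0.67 in the WT replicates, 1.495 in amo1D, 0.60 in rix1E414K and 0.98 in pob3D. Of all bins, 27.0%, 26.2% and 29.2% lay above all WT arrays in amo1D, rix1E414K and pob3D, and 24.9%, 25.4% and 32.6% below, where chance gives 25% on each side.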
